A study of Arabidopsis thaliana with 4 samples.

How the data were processed

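Expression was measured in 4 whole-plant RNA samples, 2 of wild-type Arabidopsis and 2 of the smg7b T-DNA insertion mutant, each labelled with biotin and hybridised to its own ATH1 array. The genotype and replicate number of each sample came from its title in the labels. The deposited values are 1 signal per probe set and array, a microarray intensity on a linear scale, which summarises several short probes. Per the submitters' processing notes the authors used MAS5 and GCOS, and the versions are not given in the sources used here. From the values, the 2% trimmed mean of each array is 100.01, so the signals had been scaled to a common target, and all were above 0. Such signals are not corrected for differences in curve shape between arrays, and dim probe sets keep noisy values, which can inflate the log2 fold of a gene that is off in 1 genotype.

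The signals were put on the log2 scale with no pseudocount. The 64 control probe sets of the manufacturer were left out, leaving 22746. Probe sets whose mean log2 over the 4 arrays was at or above the 40th percentile (4.32) were tested, 13648 in all. The test was limma's (version 3.58.1 in R 4.3.3) lmFit followed by eBayes with an intensity trend, with genotype as the only term and all 4 arrays, and Benjamini-Hochberg adjustment over the tested probe sets with a threshold of 0.05. The total degrees of freedom were 11.6, of which 9.63 came from the prior over probe sets. Intervals are 95% intervals from the same fit. With 2 arrays against 2, the smallest p an exact permutation test of 1 probe set allows is 0.333, so calls rest on the spread pooled across probe sets.

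Background was taken per array as the highest signal of the Bacillus control probe sets (6.57 and 6.42 in wild type, 9.21 and 6.47 in smg7b). Where every array of a genotype lay at or below it, the fold is given as at least the bright genotype's mean log2 over the mean of the backgrounds of the dim genotype's arrays. Probe sets were named only through the platform table given with the data. It pairs 13513 probe sets with 1 gene, 503 with several and leaves 8794 unnamed here, which does not mean that they lack a gene. Of the single-gene probe sets, 13436 were matched by gene identifier to the RefSeq table of assembly TAIR10.1, used for names and for which genes neighbour each other. No coordinates are printed, since the labels name no build.

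Before the data were examined, 25 gene lists were fixed by locus, recalled from general knowledge and not checked against a curated source, as were the families added later: NMD factors, reported NMD substrates, genes with conserved upstream reading frames, RNA decay, splicing, small RNA, salicylic acid and immunity, jasmonate, photosynthesis, circadian clock, heat, cold with drought and abscisic acid, touch and early stress, flowering, root, seed, cell cycle (dividing tissue), senescence, glucosinolate, flavonoid and anthocyanin, auxin, phosphate, iron, nitrate and reference genes. Lists with at least 3 tested members, 10 in all, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Only members with a single-gene probe set past the filter were tested, often a small part of a list. A gene with several probe sets was represented by the one with the highest mean. The genes named were fixed by rule: SMG7L, members of the NMD factor and substrate lists, then among called single-gene probe sets whose genotypes do not overlap, with a brighter group at or above the median of all probe sets, the 12 largest rises and the 12 largest falls; at most 2 highest and 2 lowest members of each other list; and the 5 measured neighbours of SMG7L on each side. Genes of lists added later were chosen after their values were seen.

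The analysis was tested on simulated data made from the real means and spreads, with 50 probe sets changed at each fold among 13648. It recovered 0% of those changed 1.5-fold, 60% (30) at 2-fold and 100% (50 each) at 4-fold and 8-fold. Beside these recovered ones there were 13 false calls among 13448 unchanged. Far fewer probe sets were changed than the 2771 called in the data, so the adjustment was stricter in the simulation. These shares therefore do not carry over to the data. Noise was drawn independently for each probe set, without effects shared across an array. A missing call at under 2-fold does not show that a gene is unchanged.

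Alternatives were median centring, quantile and cyclic loess normalization, other filters, a pseudocount of 32, other moderation, a replicate block, each array left out, other thresholds, an estimated correlation, the rotation test fry and the mean of a gene's probe sets. With an estimated correlation camera works with the residual degrees of freedom, 2 here, so it can hardly call a list. A call lost there decides nothing about correlation among genes. Classes of genes by transcript features linked to NMD (introns after the stop codon, long 3' untranslated regions, upstream start codons) were planned and not analysed here, because no annotation with untranslated regions was used. Plots were drawn with matplotlib 3.10.9.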

Results

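Gene expression was measured with the Affymetrix ATH1 array, which carries 22810 probe sets for Arabidopsis thaliana, in whole plants of the Columbia-0 accession. RNA from 2 wild-type samples and 2 samples of the smg7b mutant was hybridised, 1 sample to each array. The mutant carries a T-DNA insertion, a piece of bacterial DNA that can disrupt the gene it lands in. The titles of both mutant samples share the name smg7b-1. No other insertion line and no line with the gene restored was measured. Effects of other changes in that line therefore cannot be told apart from those of the insertion. All plants grew in separate pots of 5 inches under continuous light at 22 °C and 65% humidity and were taken 17 days after germination. Signals were scaled by the authors to a common level, and their 2% trimmed mean was 100.01 on each of the 4 arrays. Between 72.0% and 75.5% of the plant probe sets of an array lay above that array's background, taken as its brightest bacterial control probe set (6.42 to 9.21 signal units). The number of arrays limits the precision. The labels do not say that replicates came from separate plants or pools, so the p-values measure only the spread between these samples, which may be technical.

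The series asks which transcripts are targets of SMG7b, a factor of nonsense-mediated mRNA decay (NMD), the pathway that degrades mRNAs with premature stop codons. The gene targeted in the mutant, SMG7L (AT1G28260, chromosome 1), fell 3.11-fold. Its probe set read 49.7 and 46.8 in wild type and 16.7 and 14.4 in smg7b. The log2 change was -1.64 (SE 0.30, n = 2 per genotype), past the threshold with an adjusted p of 0.00253 in limma's moderated test with Benjamini-Hochberg adjustment. All 4 signals lay above the background of their array. Where the probe set lies relative to the insertion is not given in the sources used here, so the remaining signal does not say whether an intact transcript is made. Of the 5 neighbours on each side with a probe set of their own, 4 were too dim to be tested and 3 of the other 6 passed. Of all tested probe sets 20.3% passed, and 6 genes are too few to tell a local effect from that share. The nearest neighbour before it, AT1G28250, gave a log2 difference of 0.12 (SE 0.22, adjusted p = 0.734). AT1G28190 rose by 1.78 (adjusted p = 0.0113; 2.42 without wild-type replicate 1, 1.14 without wild-type replicate 2), AT1G28395 fell by 0.89 (adjusted p = 0.0123) and AT1G28400 rose by 0.72 (adjusted p = 0.0193). Each of these 3 calls was lost when smg7b replicate 1 was left out (adjusted p = 0.121, 0.115 and 0.214), and those of AT1G28395 and AT1G28400 also without smg7b replicate 2 (adjusted p = 0.0678 and 0.0994) and with the Actin 3'/5' ratio described at the end as a covariate (0.158 and 0.127). With that covariate AT1G28395 gave -0.64 (SE 0.30, against SE 0.21 before) and AT1G28400 gave 0.62 (SE 0.27 against 0.19), so wider errors had a part in these losses.

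Among the probe sets with a gene name here, the largest rises in smg7b were in genes for chitinases, a receptor kinase, a protease and other proteins, several of them close to background in wild type. A putative chitinase, an enzyme that cleaves chitin (symbol CHI in the reference, AT2G43570), read 1.64 and 2.21 in wild type and 1390 and 1631 in smg7b, at least 232-fold higher. AT2G44240 was at least 77.6-fold higher, AT3G49340, a cysteine protease, at least 63.6-fold and AT5G52390 at least 50.7-fold, each with both wild-type signals at or below background. The smaller falls included COR15A, a cold-induced protein of the chloroplast, at 216 and 232 in wild type against 22.3 and 26.6 in smg7b. In all, 2771 of 13648 probe sets tested passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 1543 higher and 1228 lower.

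**Figure D1:**
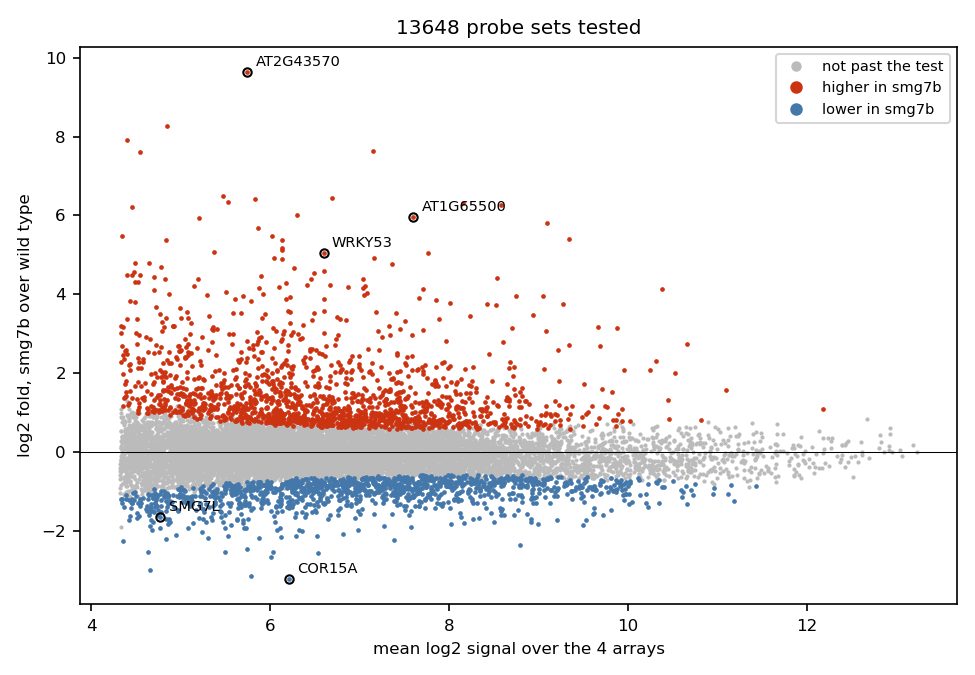
Log2 fold of smg7b over wild type (y axis) against the mean log2 signal over the 4 arrays (x axis) for the 13648 probe sets tested; red and blue points are the 1543 higher and 1228 lower probe sets past adjusted p 0.05, grey points the rest, and circles mark 5 named genes. The upper side of the plot reaches a fitted log2 fold of 9.63 (AT2G43570, whose wild-type signals lie under background, so that only the bound of at least 232-fold is measured) and the named gene farthest down, COR15A, lies at -3.20.

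The changes were larger on the higher side. Of the called probe sets, 990 were at least 2-fold higher, 339 at least 4-fold and 66 at least 16-fold. On the lower side 539 were at least 2-fold lower, 23 at least 4-fold and 0 at least 16-fold. For 9 of the called rises both wild-type arrays lay at or below background. Raising every value under the background of its array to that background left 339 probe sets at least 4-fold higher and 58 at least 16-fold. The groups did not overlap for 61.3% of the tested probe sets, against the 33.3% that chance gives on average for 2 against 2 arrays. Probe sets share the effects of their array, so this excess does not by itself show an effect of genotype. Of the calls, 55.7% were higher, and 43.9% were higher after each array was centred on its median (48.6% after quantile normalization). The number of calls depended on single arrays. It was 4325 without wild-type replicate 2, 980 without smg7b replicate 1 and 1546 without smg7b replicate 2, and 878 probe sets (674 higher, 204 lower) were called with all arrays and in each of the 4 fits that left 1 array out. Without wild-type replicate 1, without wild-type replicate 2 and with the Actin ratio as a covariate, limma gave each probe set the spread of the intensity trend alone (13648 total degrees of freedom against 11.6), so the p-values of these 3 fits are too small for probe sets that vary more.

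Among named genes, the 12 with the largest rises ranged from at least 232-fold for AT2G43570 (adjusted p = 1.12e-09) to a log2 change of 5.05 for WRKY53 (SE 0.21, adjusted p = 3.38e-08), a transcription factor known from leaf senescence and defence. As fitted, the log2 rise was 9.63 for AT2G43570 (CHI), 8.26 for AT2G44240, 7.92 for AT5G52390 and 6.33 for AT3G49340, which depends on signals under the background. With values raised to the background it was 7.86 for AT2G43570. A member of the chitinase family, AT2G43620, rose 64.8-fold from 8.66 and 11.1 to 633 and 637. AT1G65500 rose 62.3-fold to 1577 and 1490, a rise of 5.96 (SE 0.19), and AT1G13470 rose by 5.48 (SE 0.23). The lipid-transfer-like gene AT4G12490 rose by 5.19 (SE 0.34; 4.57 without wild-type replicate 1, 5.80 without wild-type replicate 2) and LUP5, an oxidosqualene cyclase, by 5.07 (SE 0.32). The receptor-like kinase AT1G51890 rose by 6.21 with the widest error of the 12 (SE 0.76), its wild-type signals being 8.04 and 0.80. Its log2 change was 4.55 without wild-type replicate 2, 7.87 without wild-type replicate 1 and 4.71 with values raised to the background. AT3G18250 rose by 6.48 (SE 0.35), and by 5.97 with values raised to the background. For AT1G51890, AT3G18250 and LUP5, 1 of the 2 wild-type arrays lay under background. Of the 20 largest rises over all probe sets, 11 had no gene name here, led by a probe set with signals of 9.21 and 10.9 in wild type and 1952 and 2047 in smg7b (266070_at).

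The 12 named genes with the largest falls ran from COR15A, which fell by 3.20 (SE 0.22, adjusted p = 1.56e-06 in limma), to ARR15, a cytokinin response regulator, which fell by 1.96 (SE 0.34, adjusted p = 0.00191). AT4G25780, of the family of pathogenesis-related protein 1, fell by 2.99 (SE 0.36). AT5G62360, an inhibitor of invertase or pectin methylesterase type, fell by 2.65 (SE 0.28), AT3G26960 by 2.56 (SE 0.25) and the glycosyltransferase gene AT5G05890 by 2.26 (SE 0.37). The expansin-like gene EXLB1 fell by 2.12 (SE 0.26), the auxin-response repressor IAA29 by 2.09 (SE 0.30) and COR15B, the close relative of COR15A, had a change of -2.06 (SE 0.22). AT1G62290, an aspartic protease gene, and AT4G12980 changed by -2.02 and -2.01. AT4G35335 fell by 2.18 (SE 0.52, adjusted p = 0.0123), with smg7b signals of 8.997 and 38.3, and this call was lost without smg7b replicate 1 (-1.14, adjusted p = 0.0746; -3.23 without smg7b replicate 2) and with the Actin 3'/5' ratio as a covariate, where the change was -0.87 (SE 0.41, adjusted p = 0.171). Among unnamed probe sets, 252607_at fell by 3.12 and 256503_at fell by 2.54.

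**Figure D2:**
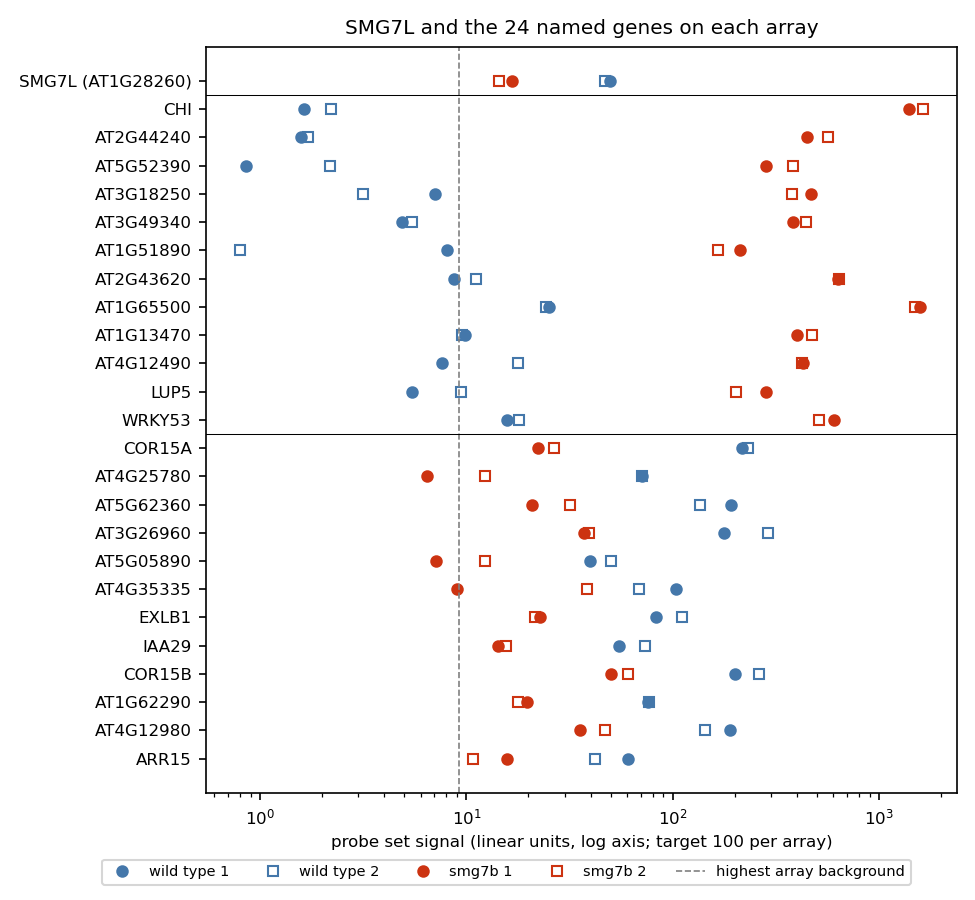
Signals on each array (x axis, linear units on a log axis) of SMG7L, the 12 named genes with the largest rises and the 12 with the largest falls; blue points are wild-type arrays, red points smg7b arrays, circles replicate 1 and squares replicate 2, and the dashed line is the highest of the 4 array backgrounds (9.21). In none of the 25 genes do the wild-type and smg7b signals overlap, as the naming rule requires for the 24.

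The factors of the NMD pathway itself were compared next. Of 6 tested members (of 14 listed), SMG7L alone passed the threshold, and also when adjusted over the list alone. UPF3 and Y14 gave log2 differences of 0.02 (SE 0.20) and 0.02 (SE 0.19), UPF2 gave 0.54 (SE 0.22, adjusted p = 0.0998), and the exon junction partners BTZ1 and BTZ2 gave -0.47 (SE 0.35) and -0.46 (SE 0.38). The list did not shift as a set (camera adjusted p = 0.862). Without wild-type replicate 2 the values of UPF2, BTZ1 and BTZ2 passed the threshold (adjusted p = 0.0499, 0.0216 and 0.00459), in a fit whose p-values are too small.

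Transcripts listed as reported NMD substrates, from memory and not checked against a curated table, gave 0 calls in limma among 4 tested (of 17 listed), 0 also adjusted over the list alone. The protein kinase gene AT5G45430 gave a log2 difference of -0.03 (95% interval -0.53 to 0.47), the initiation factor EIF5 (AT1G36730) 0.03 (-0.49 to 0.55) and AT2G29210 0.04 (-0.44 to 0.51), with BTZ1 as above. Their set test gave a camera adjusted p of 0.862. A probe set reads the summed transcripts it matches, so a change in 1 isoform among several was not resolved. Genes with a conserved upstream reading frame went both ways, with 2 of 7 tested (of 17 listed) called, the same number adjusted over the list alone. Of all tested probe sets, 20.3% were called. The methyltransferase gene PMEAMT (AT1G48600) fell by 1.30 (SE 0.20, adjusted p = 7.53e-04) and BZIP53, a transcription factor gene, rose by 0.94 (SE 0.22, adjusted p = 0.0117). The BZIP53 call was lost without smg7b replicate 1 (adjusted p = 0.169), without smg7b replicate 2 (0.0587) and with the Actin ratio as a covariate (0.242), where it was smaller with a wider error, 0.54 (SE 0.29). Of 7 tested general RNA decay factors (of 18 listed) 0 passed, and 0 adjusted over the list alone, the deadenylase gene CCR4A giving 0.47 (SE 0.19, adjusted p = 0.0965) and the helicase gene RH6 -0.33 (SE 0.21). The upstream reading frame and RNA decay lists each had a camera adjusted p of 0.862.

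All 3 tested genes of the salicylic acid and immunity list rose in smg7b. The list has 32 members, of which only 3 had a single-gene probe set, so its set test speaks for these 3 only. WRKY53 rose by 5.05, GRX480, a glutaredoxin induced by salicylic acid, by 4.11 (SE 0.39) and SAG101, a lipase-like partner in immune signalling, by 1.84 (SE 0.32). The wild-type signals of GRX480 were 4.08 and 9.56. Its rise was 3.77 with values raised to the background, 4.73 without wild-type replicate 2 and smaller than 4.11 without wild-type replicate 1. The median was 4.11, all 3 also passed adjusted over the list alone, and the list shifted upward with a camera adjusted p of 1.42e-04. With the correlation among its genes estimated from these arrays the shift was not called (adjusted p = 0.619 with an estimated correlation). That form of camera has only the 2 residual degrees of freedom and could hardly call any list. The lost call therefore does not show that correlated genes made the shift. The rotation test fry called the list (adjusted p = 0.0468). In the jasmonate list, 1 of 2 tested genes rose, the same number adjusted over the list alone. It was the thionin gene THI2.1, which went from 11.3 and 17.2 to 256 and 240, a rise of 4.15 (SE 0.26, adjusted p = 7.69e-07), while the defensin gene PDF1.2 gave -0.29 (SE 0.28, adjusted p = 0.494).

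All 4 tested genes of the cold, drought and abscisic acid list fell. The list has 23 members, so its set test speaks for these 4 only. COR15A fell by 3.20 and COR15B fell by 2.06, the dehydrin gene LTI30 by 1.11 (SE 0.34, adjusted p = 0.0402) and COR47, another dehydrin gene, by 0.80 (SE 0.20, adjusted p = 0.0145). The median was -1.58, all 4 passed adjusted over the list alone, and the shift had a camera adjusted p of 2.52e-04. It was not called with the correlation estimated (adjusted p = 0.619 with an estimated correlation), a form of camera with only 2 residual degrees of freedom. The rotation test fry called it (adjusted p = 0.0468). The calls of LTI30 and COR47 were lost without smg7b replicate 1 (adjusted p = 0.394 and 0.228) and with the Actin ratio as a covariate (0.454 and 0.162), where LTI30 gave -0.58 (SE 0.43) and COR47 -0.61 (SE 0.28 against 0.20 before). Also lost were that of COR47 without smg7b replicate 2 (0.0866) and that of LTI30 without the filter on dim probe sets (0.101).

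**Figure D3:**
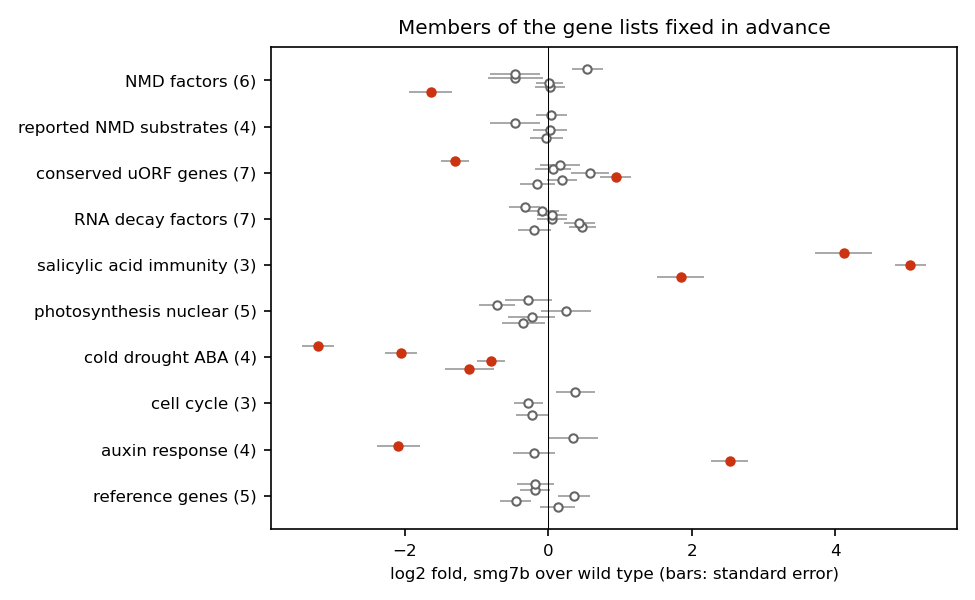
Log2 fold of smg7b over wild type (x axis) for each tested member of the 10 gene lists with at least 3 tested members; each point is 1 gene with its standard error as a bar, filled where the gene passed adjusted p 0.05 over all probe sets, and the number of tested members is in parentheses. The 3 genes of the salicylic acid and immunity list lie between 1.84 and 5.05, the 4 of the cold, drought and abscisic acid list between -3.20 and -0.80.

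The auxin list held opposite changes. The auxin-conjugating enzyme gene GH3.3 rose by 2.53 (SE 0.26, adjusted p = 3.50e-05) and IAA29 fell by 2.09, with 2 of 4 genes called, the same number adjusted over the list alone, and a camera adjusted p of 0.862. In the flavonoid and anthocyanin list DFR, which encodes dihydroflavonol reductase, rose by 2.09 (SE 0.26, adjusted p = 1.55e-04) and UGT78D2 gave 0.37 (SE 0.23; adjusted p = 0.286, and 0.0482 without wild-type replicate 2), so that 1 of 2 passed, as it did adjusted over the list alone. The zinc finger gene ZAT10, the 1 tested gene of the touch and early stress list, rose by 2.45 (SE 0.27, adjusted p = 7.09e-05), also adjusted over the list alone. ROF2, the 1 tested gene of the heat list, rose by 0.97 (SE 0.23, adjusted p = 0.0113; also adjusted over the list alone), a call lost without smg7b replicate 1 (0.0617) and without smg7b replicate 2 (0.119). In the glucosinolate list 0 of 2 genes passed over all probe sets and 1 adjusted over the list alone, UGT74B1 giving 0.67 (SE 0.22, adjusted p = 0.0522) and BCAT4 -0.26 (SE 0.21). UGT74B1 passed after quantile or cyclic loess normalization (adjusted p = 0.0392 and 0.0282), at the 60th percentile filter (0.0433), with a pseudocount of 32 (0.0461), with robust moderation (0.0497), without wild-type replicate 2 (1.42e-04) and with the crossed replicate block (0.00910).

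Nuclear photosynthesis genes gave 0 calls in limma among 5 tested (of 36 listed), 0 also adjusted over the list alone (camera adjusted p = 0.862). The Calvin cycle enzyme gene PRK gave -0.72 (SE 0.25, adjusted p = 0.0680) and the photosystem gene PSAE1 0.24 (SE 0.35; adjusted p = 0.664, and 0.00304 without wild-type replicate 2). PRK passed the threshold after median centring (adjusted p = 0.0440), after quantile normalization (0.0224), without wild-type replicate 1 (9.95e-04) and without wild-type replicate 2 (0.00494). Of 3 dividing-tissue genes and 5 reference genes 0 passed, 0 also adjusted over each list alone, each list having a camera adjusted p of 0.862. The reference genes UBC21 and TIP41 gave -0.46 (SE 0.22) and 0.36 (SE 0.22), UBC21 passing without wild-type replicate 2 (adjusted p = 0.0130). Neither of the 2 tested splicing factors passed. The small RNA, circadian clock, flowering, root and iron lists had 1 tested gene each, which did not pass (adjusted p from 0.193 to 0.992). The splicing list and these 5 also had 0 genes past the threshold adjusted over the list alone. The seed, senescence, phosphate and nitrate lists had 0 tested members.

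Control probe sets for the 2 ends of abundant transcripts differed between the genotypes. The 3'/5' signal ratio of Actin was 2.22 and 8.62 in wild type and 25.8 and 9.65 in smg7b. That of GAPDH was 0.960 and 1.22 against 2.26 and 1.41, and that of ubiquitin, which overlapped, 1.11 and 2.01 against 2.48 and 1.57. With the Actin ratio as a covariate 1709 probe sets passed, 1106 higher and 603 lower, and SMG7L fell by 1.68 (adjusted p = 0.00714), in a fit whose p-values are too small. Within a genotype the arrays correlated across tested probe sets at r = 0.964 (wild type) and 0.977 (smg7b), and between genotypes at 0.839 to 0.888. These correlations are across probe sets, which are not independent replicates.

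**Figure D4:**
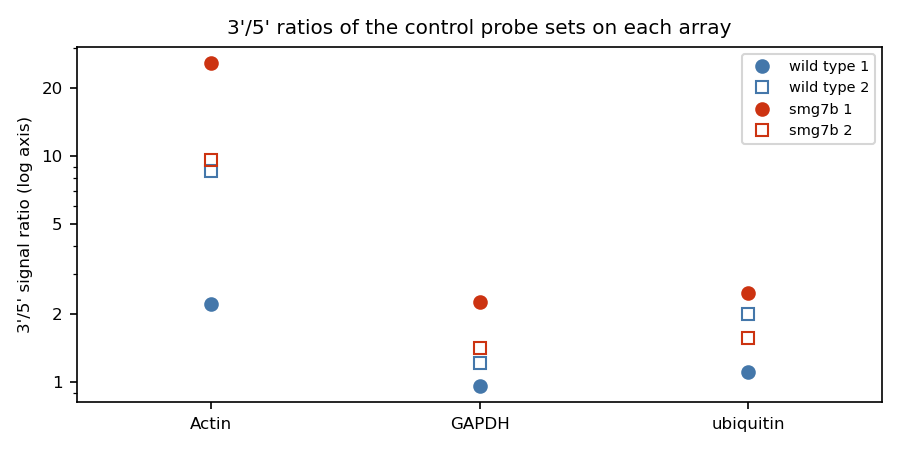
Ratio of the 3' to the 5' control probe set signal (y axis, log axis) for Actin, GAPDH and ubiquitin on each array; blue points are wild type, red points smg7b, circles replicate 1 and squares replicate 2. The Actin ratio runs from 2.22 in wild-type replicate 1 to 25.8 in smg7b replicate 1, and the replicate 2 arrays lie close together at 8.62 and 9.65.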

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

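The tests of RNA integrity and of reported NMD substrates on the 4-fold higher probe sets, the count of other splits, the Actin covariate and the set test of chloroplast-encoded genes were chosen only after the result was seen; the test of these genes within each genotype was written after their set shift and before its own result.

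3 control signals outside the comparison of genes were higher on both smg7b arrays than on both wild-type arrays. The 25S ribosomal RNA probe set was 1.90-fold higher (663 and 704 in wild type, 1104 and 1531 in smg7b). The Actin 3'/5' ratio was 3.61-fold higher and the GAPDH 3'/5' ratio 1.65-fold higher, as geometric means.

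A higher 3'/5' ratio is what shorter RNA gives, so a difference in RNA integrity may have shaped part of the comparison. Probe sets at least 4-fold higher in smg7b replicate 1 than in wild-type replicate 1, 374 in all, were looked at in the replicate 2 arrays, whose Actin ratios differ 1.12-fold against 11.7-fold in the first pair. Their median log2 difference there was 2.46 (bootstrap 95% interval over probe sets 2.33 to 2.65) and 372 were higher. Within a genotype the same probe sets differed by a median of 0.07 (smg7b) and 0.31 (wild type), although the Actin ratio differs there too, which argues against integrity as the whole cause of these rises. The 4 tested substrates had a mean log2 fold of -0.11, with a 95% interval of -0.40 to 0.18 if the genes vary independently, below the 0.58 set for a shared loss of decay, and an upper limit of at most 0.54 in the 15 alternatives that tested all 4, 3 of them with too narrow intervals. That mean differed between the wild-type arrays (7.28 and 6.75), and the interval from its spread between arrays, -1.25 to 1.03, leaves a shared loss open. The difference in 25S signal, an effect of the plants' condition apart from the insertion, and a part of the change owed to integrity were not excluded.

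Chloroplast-encoded genes were higher in smg7b as a set with all arrays (median log2 0.29 over 68 genes, camera adjusted p = 0.0227, and adjusted p = 0.683 with an estimated correlation). The direction turned without wild-type replicate 1 (median -0.07, adjusted p = 0.332), the call was lost without smg7b replicate 1 (0.394), and with the Actin ratio as a covariate the set was called lower (median -0.27, adjusted p = 0.0214, in a fit with 1 residual degree of freedom). Single calls were 1 rise, atpH by 0.83, and 1 fall, psaA at -0.87. Both calls were lost without smg7b replicate 1 (adjusted p = 0.345 and 0.370) and with the Actin covariate (atpH 0.84, SE 0.36 against 0.23 before, adjusted p = 0.117; psaA -0.66, SE 0.31 against 0.23, adjusted p = 0.157), that of atpH also without smg7b replicate 2 (0.165) and without the filter (0.0883). Within both genotypes the array with the higher Actin ratio had the higher median, by 0.253 in smg7b and 0.69 in wild type. Each is a difference between single arrays, over genes that vary together (estimated correlation 0.568), so it cannot be set against the ordinary spread between arrays and decides nothing about RNA integrity. RNA integrity and a biological difference in organelle transcripts both stay open, the second untested.

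Of the 3 ways to split the 4 arrays into pairs, 1, the real one, gave as many called probe sets, 2771 against at most 0 in limma (12 and 40 at an unadjusted p under 0.05). In the other splits each pair holds 1 array of each genotype, so any genotype difference widens the spread and few calls are fixed in advance. The contrast with 2771 therefore does not test the grouping. The splits are also too few for a share under 0.05.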

How the results depend on the processing

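The background floor, the Actin covariate, the crossed block and the added lists were chosen after seeing the data, and all other alternatives beforehand. SMG7L stayed lower and past the threshold in each alternative that tested it, with log2 changes from -1.74 to -0.76 (the latter with a pseudocount of 32) and adjusted p up to 0.0208; at the 60th percentile filter it was not tested. Of 63 called genes that the text names, 0 turned sign and 18 lost the call in at least 1 alternative. Where the genotypes do not overlap, as the rule for the largest rises and falls required, leaving out 1 array cannot turn the sign. The replicate blocks leave the fold unchanged, so the 0 was partly fixed in advance. Genes that an alternative did not test, as SMG7L and others at the 60th percentile filter, were not counted as losing the call. The count of called probe sets, 2771, ranged from 980 to 4325 with 1 array left out, in fits where the lone array was assumed to vary like the others, and was 1709 with the Actin covariate and 1563 for a fold of 2 or more with no overlap and no test. The cause was not tested, except that fewer arrays enter the first and that 3 of these fits (without either wild-type array, or with the Actin covariate) took their spread from the trend alone (13648 degrees of freedom), which makes their p-values too small. Same-numbered arrays deviated apart (correlation -0.146 over tested probe sets). From replicate 1 to replicate 2 the Actin ratio rose in wild type and fell in smg7b, and the labels do not say what the numbers share. The correlation therefore does not decide whether the numbers pair the samples. With the replicate block 2488 probe sets were called (1402 higher, 1086 lower), and SMG7L changed by -1.64. With the numbers crossed 3988 were called.

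Of the gene lists, 2 passed with the preset correlation, 3 without a filter (13 lists tested, 1 more being flavonoid and anthocyanin genes, higher, adjusted p 0.00250), 1 at the 60th percentile filter, where fewer genes are tested, and 0 with the correlation estimated (adjusted p 0.619 for the immunity and for the cold lists). The estimated form has only 2 residual degrees of freedom and could hardly call any list. The rotation test fry called the immunity and the cold lists (adjusted p 0.0468 each). Uncalled lists near 0 turned direction: auxin without a filter (adjusted p 0.929); NMD factors, substrates and upstream reading frames at the 60th percentile (0.974); substrates, upstream reading frames and reference genes with the Actin covariate (0.834). With 1 array left out the adjusted p ranged from 0.812 to 0.978 for substrates, 0.911 to 0.978 for upstream reading frames and for RNA decay, and 0.788 to 0.968 for auxin. Chloroplast-encoded genes turned lower with the Actin covariate (adjusted p 0.0214) and ranged from 4.00e-06 to 0.394 with 1 array left out, turning without wild-type replicate 1.

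Uncalled genes turned sign as follows, in log2. Median centring gave -0.0690 for UPF3, -0.0778 for Y14, -0.0655 for EIF5 and -0.0549 for AT2G29210, and quantile normalization -0.0669, -8.31e-04, -0.0152 and -0.0578. Cyclic loess gave 0.0224 for AT5G45430. The Actin covariate gave -0.0383 for UPF3, -0.18 for Y14, 0.39 for BTZ1, 0.58 for BTZ2, 0.37 for AT5G45430, -0.13 for AT2G29210, 0.0474 for RH6, -0.37 for PSAE1, -0.0293 for UGT78D2 and -0.00444 for AT1G28250. With 1 array left out the ranges were -0.0782 to 0.13 for UPF3, -0.13 to 0.16 for Y14, -1.05 to 0.13 for BTZ2, -0.36 to 0.30 for AT5G45430, -0.29 to 0.34 for EIF5, -0.13 to 0.21 for AT2G29210 and -0.17 to 0.66 for PSAE1. The causes were not tested. The NMD feature classes were not run. Signal over background limits dim genes: 72.0% to 75.5% of probe sets lay above it.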

Other observations

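The gene groups here were chosen after their values were seen, apart from the test of neighbouring genes, which was written beforehand.

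In further groups of named genes most tested members rose in smg7b, though no group was called with an estimated correlation. That form of camera has only 2 residual degrees of freedom here and could hardly call any group, so it does not decide between them. Only a few members of each list with a single-gene probe set were tested, and some, dim in wild type, passed the filter on the mean over all arrays only through their smg7b signals, so the rise partly decides which members count. Of 5 tested chitinase genes (of 15) 4 rose: AT2G43570 and AT2G43620, AT4G01700 by 3.01 and AT2G43590 by 1.39, while AT3G47540 gave 0.41 (camera adjusted p = 1.51e-06, adjusted p = 0.132 with an estimated correlation). The call of AT2G43590 was lost without smg7b replicate 2 (adjusted p = 0.226) and without the filter (0.0650). Of 6 tested berberine bridge enzyme-like oxidases (of 22) 4 rose, AT1G26380 by 4.48, AT4G20860 by 2.98, AT4G20830 by 2.17 and AT2G34810 by 1.43 (camera adjusted p = 5.00e-04, adjusted p = 0.132 with an estimated correlation). The uncalled AT5G44400 gave 0.25 and AT5G44410 gave -0.41. Of 5 tested leucine-rich repeat receptor kinases of subfamily I (of 31) 4 rose, AT1G51890, AT1G51790 by 3.46, AT5G59670 by 2.44 and AT5G59680 by 1.61, while AT1G51805 gave 0.19. This list had a camera adjusted p of 6.60e-05 (adjusted p = 0.132 with an estimated correlation) and was not called without the filter (0.132, median -0.19). Without the members that prompted the lists the camera adjusted p was 0.00540, 0.00411 and 5.00e-04 for chitinases, oxidases and kinases (adjusted p = 0.153, 0.151 and 0.132 with an estimated correlation). Without the filter as well, chitinases and kinases were not called (0.0610 and 0.222, median -0.20 for the kinases). The fitted rise of AT1G26380 was 3.70 without wild-type replicate 1 and 5.27 without wild-type replicate 2.

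Genes were also grouped by the letters of their symbols, and 4 of 41 such families passed with the preset correlation (each with adjusted p = 0.700 with an estimated correlation). The estimated correlations of these 4 (-0.0918 to -0.0591) lie below the preset 0.01, so a higher correlation is not why their calls were lost. These families hold only genes with a single-gene probe set named by symbol, not whole gene families. Of 4 tested WRKY transcription factors 3 rose, WRKY53, WRKY47 4.91-fold and WRKY6 4.89-fold (camera adjusted p = 0.00362). The 5 beta-tubulin genes so named all fell, TUB5 by 1.48, TUB6 by 1.13, TUB1 by 1.12, TUB7 by 0.74 and TUB9 by 0.70 (camera adjusted p = 0.00362), with the same direction of the median under each scaling. The calls of TUB1, TUB7 and TUB9 were each lost without smg7b replicate 2 (adjusted p = 0.0718, 0.0748 and 0.115), and those of TUB7 and TUB9 also without smg7b replicate 1 (0.223 and 0.359). That of TUB7 was lost with the Actin covariate too (0.141), at -0.61 with a wider error (SE 0.28 against 0.19), while the family stayed called (median -1.03, 0.00156). That of TUB9 was lost too without wild-type replicate 2 (0.0958), with cyclic loess (0.0546), without the filter (0.0598) and without the trend (0.0793). Of 4 such COR genes 3 fell, COR15A, COR15B and COR47 (camera adjusted p = 0.00742). Of 4 such jacalin-related lectin genes 3 rose, JAL23 by 1.84, JAL33 by 0.87 and JAL34 by 0.78 (camera adjusted p = 0.0221). JAL33 and JAL34 lost their calls without smg7b replicate 1 (0.203 and 0.190) and without smg7b replicate 2 (0.109 and 0.0801), JAL33 also without wild-type replicate 2 (0.0553) and JAL34 with the Actin covariate (0.133), at 0.66 with a wider error (SE 0.29 against 0.20). The family, with a median of 0.83, was not called without wild-type replicate 1 (0.0929), without wild-type replicate 2 (0.0976) or with the Actin covariate (0.0540), where its median was 0.92, 0.73 and 0.89. Among 10 tested mitochondrial transcripts (of 16) 3 rose, ccb382 by 1.19, nad4L by 1.13 and ccb452 by 0.82 (camera adjusted p = 0.00234, adjusted p = 0.389 with an estimated correlation), and the set, with a median of 0.69, was not called with the Actin covariate (median 0.27, adjusted p = 0.325) or without wild-type replicate 1 (median 0.52, adjusted p = 0.0849). The calls of nad4L and ccb452 were lost without smg7b replicate 1 (0.197 and 0.387), without smg7b replicate 2 (0.0756 and 0.0633), without the filter (0.0650 and 0.0756) and with the Actin covariate (0.132 and 0.707), where nad4L gave 1.06 (SE 0.47 against 0.29) and ccb452 0.26 (SE 0.32 against 0.26). The call of ccb452 was lost also with median centring (0.0601), quantile normalization (0.0653), cyclic loess (0.0502), no trend (0.0697), the replicate block (0.05002) and without wild-type replicate 1 (0.125).

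Rises in neighbouring genes may be more frequent than chance places them. Of 7197 named genes in chromosome order, 92 neighbouring pairs were both called higher, against a mean of 76.7 and a highest value of 109 in 10000 shuffles (one-sided permutation p = 0.032, 0.064 adjusted over both directions). For calls lower the number was 54 against a mean of 49.3 (permutation p = 0.25). The excess did not pass the adjustment. Runs of neighbours include AT5G52740 to AT5G52760, 3 genes with rises of 3.52 to 4.38, and AT1G72890 to AT1G72940, 4 genes with rises of 0.92 to 2.68.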
